A study of Mus musculus with 2 samples.

How the data were processed

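DNase-seq was carried out on testis tissue of male B6CASTF1/J mice at 14 days of age. The labels give 2 libraries, numbered as biological replicates 1 and 2 of 1 group. The label of replicate 1 names 3 males and that of replicate 2 gives no number of animals, and both carry the same donor label, so the spread between the libraries may be in part technical. The files of the 2 libraries differ in number and position of their regions, and each library was counted once.

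Per library the deposited text descriptions list a longer and a shorter peak list, a list of footprints and a track of the false discovery rate (FDR) of the cut rate, all on mm10 and each made from the alignments of that library alone, not from pooled libraries. The footprints were made from the FDR track and the alignments, per these descriptions. The aligner, the peak and footprint callers, their versions and the placing of repeated reads are not given in the sources used here. The value of a peak is a signal column of the deposited peak files, set by the authors. In each library 100% of its values below 1 were whole multiples of 1 smallest step within 0.05 steps (0.00538 in replicate 1 and 0.00377 in replicate 2), so the values behave as whole units scaled per library. What 1 step stands for is not given in the sources used here. The FDR track holds a q-value per stretch of bases, deposited by the authors only below 0.05, over 31.0 and 34.9 Mb. The p-value column of the deposited footprint files holds 0.01 in all rows, a threshold, so only footprint positions were used. Each peak was set against the FDR track: the lowest FDR under a peak reached 0.0499 in the longer lists and 0.000992 in the shorter ones. The longer lists (FDR below 0.05) were used throughout, and the shorter ones (FDR below 0.001), known only after the data were examined, as an added alternative. A peak's value is the authors' own and was used to rank and describe peaks.

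Coordinates were compared with GRCm38.p6, the same build as mm10. All peaks and footprints lay on the named chromosomes and none beyond a chromosome's end. Genes were the 21911 protein-coding genes of GENCODE M21 on chromosomes 1 to 19, X and Y, with 1 gene kept per symbol. A promoter window held 1000 bp on each side of an annotated transcription start, and a gene's promoter value was the highest value among peaks that overlap its windows, or 0. A gene was called open where both libraries had such a peak. Absence of a peak means only that none was listed below the FDR limit. A window can hold the start of another gene, and peaks shared in this way were counted. Distal peaks lay within 50 kb of a start and outside all promoter windows.

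Before the data were examined, 19 gene lists were fixed from textbook knowledge, along with the rule that olfactory and vomeronasal receptor genes form another list. They cover spermatogonia, meiotic prophase, pachytene spermatocytes, spermatids, the piRNA pathway, Sertoli, Leydig, peritubular myoid, interstitial stroma, endothelial, leukocyte and erythroid cells, epididymis, housekeeping genes, liver, brain, skeletal muscle, epidermis and Hox genes. Of the meiotic list, Iho1 was not matched by symbol, and all symbols of the other lists were. Mybl1 and Piwil1 are in both the pachytene and the piRNA lists. Each list was set against 10000 random lists of as many protein-coding genes. Its percentile is the share of random lists below it with ties split evenly, and a list was called high or low at the 99th or 1st percentile. These percentiles describe the 2 libraries and are not p-values. An alternative matched the random lists on the decile of observed over expected CpG in the promoter. The difference between the libraries was the median log2 ratio of replicate 2 over replicate 1 over a list's open genes, centred on all open genes and set against lists matched on the decile of the mean value.

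Genes were named by a rule fixed before the data were examined: per list the 3 open genes with the highest mean value and the first 2 by alphabet with no promoter peak in either library, the 10 highest promoters of all genes, the 5 longest peaks per library, and the first 10 list genes by alphabet with a peak in a single library. Of the last, Cd14 had 0.441 in replicate 1 alone and Actg2 0.291 in replicate 2 alone. Of the genes this rule names, 3 are not reported here. The strongest peak and the genes that share peaks were named after their values were seen.

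Overlaps counted from 1 bp with bedtools 2.31.1. Chance overlap came from 20 random placements of the peaks on their own chromosome outside assembly gaps, and 1 placement of all footprints within shared peaks of the same chromosome. For consensus sequences, also fixed beforehand, each footprint lying fully inside a peak was extended by 5 bp on each side and set against a window of equal width moved 50 bp within the same peak, in 219264 and 280365 pairs, and matches on either strand were counted on the genome sequence. Footprints that left no room for the moved window were left out. A moved window could overlap another footprint, and such windows were kept. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The computations were tested on simulated data. Of 11115 promoters planted as open 100% were recovered, a planted list of 20 genes reached percentile 99.99, 0.5% of 200 lists with no planted change passed a limit, a planted log2 shift of 0.5 between the libraries came back as 0.62 over 20 genes at percentile 100, a planted share of 79.6% shared peaks came back as 79.6%, and a sequence planted in 29.9% of 4995 footprints was found in 29.9%.

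The alternatives were promoter windows of 500 and 2500 bp, the 5' end of the gene in place of all starts, the stronger peaks (at or above the median value), a reciprocal overlap of 50%, equal numbers of peaks, distal windows of 20 kb, footprints not extended, control windows at 100 bp, each library alone, and, chosen after seeing the data, the stricter peak list. Depth in reads is unknown, so no interval on a share of reads was made.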

Results

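Open chromatin was mapped by DNase-seq, in which DNase I cuts exposed DNA and the cut ends are sequenced, in whole testis tissue of male B6CASTF1/J mice, a first-generation cross of a C57BL/6 and a castaneus-derived strain, at 14 days of age. The labels describe 1 group with 2 biological replicates, and replicate 1 is described as tissue of 3 males. No treatment, genotype or age is compared, so the values below describe this tissue and the spread between its 2 libraries, and no test between groups was possible. Peak values are the authors' own, and all coordinates are in mm10. The lists held 101172 peaks in replicate 1 and 117359 in replicate 2 (mean 109266 ± 11446, SD, n = 2), covering 19.7 and 22.8 Mb. The median peak was 192 and 191 bp wide. Its value corresponded to 101 and 134 of the smallest steps in which the values of each library are written. If each step is an independent event, that is a counting error of 9.95% and 8.64% of the median peak in the 2 libraries. Depth in reads is unknown from these files.

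The promoters of meiotic genes were open throughout. All 31 matched genes of the meiotic prophase list, which build the synaptonemal complex and make and repair meiotic double-strand breaks, had a promoter peak in both libraries, as did all 20 genes of the piRNA pathway, which silences transposons in germ cells. Over all 21911 protein-coding genes the share was 68.7% (15056 genes). Among 10000 random lists of the same size, the open share of the meiotic list stood at percentile 100 and that of the piRNA list at 99.965. Matched on promoter CpG content, which by itself goes with open promoters, the percentiles were 99.9 and 99.5. The median of the highest promoter peak value was 5.00 ± 0.39 (SD, n = 2) over the meiotic list and 4.73 ± 0.15 over the piRNA list. The meiotic median stood at percentiles 99.51 and 99.36 in the 2 libraries, and at 99.32 and 98.55 when matched on CpG. That of the piRNA list lay inside the limits, at 96.85 and 97.2. Prdm9, the histone methyltransferase that places recombination sites, had 15.9 ± 3.2, with its peak at chromosome 17, 15564301 to 15564540 in replicate 1, across the 5' end of the gene. Meioc, needed to hold cells in meiotic prophase, had 12.4 ± 0.41, and Msh5, a crossover factor, 11.9 ± 0.48. Among piRNA genes, Tdrd7 reached 14.7 ± 2.6, Exd1 14.3 ± 0.41 and Tdrkh 12.8 ± 0.23. The peaks of Meioc and Tdrd7 lay at annotated starts away from the 5' end of the gene, and with that end alone the values were 0 and 0.174. The Exd1 peak also lay in the promoter window of Chp1, and 4 of the 31 meiotic and 2 of the 20 piRNA genes shared their highest peak with another protein-coding gene in this way.

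Promoters of genes for the earlier and later stages of spermatogenesis were open to different extents. Of the 20 spermatogonial genes, 18 had a promoter peak in both libraries and 1 in a single library, a share of 90.0% at percentile 98.4. Etv5, a transcription factor of spermatogonial stem cells on chromosome 16 (22381309 to 22439719), had a value of 19.1 ± 1.8, Id4 6.89 ± 0.32 and Dmrt1 5.51 ± 0.66, whereas Nanos2 had none. Of the 18 genes of the pachytene list, 16 were open in both (percentile 97.0), led by Hspa2 at 17.9 ± 2.1, Cdc25c at 10.2 ± 0.40 and Tbpl1 at 9.99 ± 0.36, with no peak at Acr or Aurkc. Neither list passed the limit of the 99th percentile, but the spermatogonial list passed it in replicate 2 taken by itself (99.5), with windows of 2500 bp (99.35) and with the 5' end alone (99.5), and came to 92.99 when matched on CpG, 95.6 with the stronger peaks and 93.8 with the stricter peak list. By contrast, 10 of 25 genes of the spermatid list, which package the sperm nucleus and build the flagellum and acrosome, were open in both libraries and 14 in neither. That share of 40% stood at percentile 0.175, and at 1.985 against lists matched on CpG, at 1.73 with windows of 2500 bp and at 1.63 with the stronger peaks, which are no longer beyond the limit. The spermatid genes with the highest values were Odf2 at 21.4 ± 2.4, Catsper2 at 11.6 ± 1.3 and Tssk6 at 10.1 ± 3.4. The Tssk6 values come from different peaks on chromosome 8, at 69903181 to 69903460 in replicate 1 and 69901581 to 69901800 in replicate 2. Its SD is therefore not the spread of a single peak. Of the 10 open spermatid genes 5 shared the peak with another gene, among them Catsper2 with Pdia3 and Tssk6 with Ndufa13 and Yjefn3. Acrv1 and Akap4 had no promoter peak.

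Of the 5 lists for somatic cell types of the testis, that of Sertoli cells passed a limit by its open share. The others lay inside the limits, except that of Leydig cells when matched on CpG. In the Sertoli cell list, 19 of 20 genes had a promoter peak in both libraries, at percentile 99.7, and at 99.96 when matched on CpG. The median promoter value of the list, 1.74 ± 0.21, was lower than that of the meiotic list, 5.00. Median promoter CpG (observed over expected) also differed, at 0.438 and 0.640. By its median value the Sertoli list lay inside the limits, at percentiles 54.5 and 67.1 in the 2 libraries. When matched on CpG these were 76.6 and 87.3. Among single genes, Ctsl, a protease secreted by Sertoli cells, had 6.50 ± 0.75, Clu 3.51 ± 0.40 and Wt1, a transcription factor of Sertoli cells, 3.39 ± 0.19, and Rhox5 had none. The Sertoli list came to percentile 98.7 with the stronger peaks alone and to 93.8 with the peak list at the stricter false discovery rate, where 80.0% of its genes stayed open. The peritubular myoid list was open at 11 of 12 genes (percentile 96.1), with Tpm1 at 10.1 ± 0.51, Mylk at 6.78 ± 0.28 and Tpm2 at 2.68 ± 0.81; at the 5' end alone Tpm1 had 1.82. The remaining gene, Actg2, had a peak in replicate 2 alone, and in that library by itself the list stood at percentile 99.4. The Leydig cell list was open at 11 of 14 genes (percentile 77.3, and 99.1 when matched on CpG). Scarb1, a receptor for high-density lipoprotein, had 3.76 ± 1.0 and the electron carrier Fdx1 3.34 ± 0.54, while Hsd3b1 and Akr1c14 had none. Of the interstitial stroma list 10 of 12 genes were open (percentile 85.3), with Fn1 at 5.09 ± 0.058, Pdgfra at 2.37 ± 0.47, Col1a1 at 2.09 ± 0.18 and no peak at Lum. Of the endothelial list 9 of 12 were open (percentile 65.3), with Egfl7 at 1.67 ± 0.34, Vwf at 1.3 ± 0.18, Erg at 1.27 ± 0.068 and none at Emcn or Pecam1. The Egfl7 peak was shared with Gm20532. At the 5' end alone Egfl7 and Vwf had no peak, Pdgfra had 1.24 and Tpm2 1.08, and Erg had 0.160 in windows of 500 bp.

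Genes of blood cells, epididymis, liver and epidermis mostly lacked promoter peaks. Only 2 of 14 leukocyte genes were open in both libraries, Fcer1g at 0.733 ± 0.026 and Ptprc at 0.259 ± 0.089, and none was found at Adgre1 or C1qa. The erythroid list was open at 2 of 10 genes, among them Epor at 0.982 ± 0.058, with no peak at Alas2 or Ermap. The epididymis list was open at 1 of 10, Cst8 at 0.285 ± 0.030, and Adam7 and Crisp1 had no peak. In the liver list 3 of 15 were open, Apoa2 at 1.36 ± 0.063, Apob at 1.16 ± 0.23 and Ahsg at 0.441 ± 0.015, and Alb and Apoa1 had none. In the epidermis list 3 of 12 were open, Krt10 at 4.66 ± 0.24, Krt1 at 0.391 ± 0.13 and Trp63 at 0.385 ± 0.0050, and Dsg1a and Dsg3 had none. In windows of 500 bp Fcer1g and Apoa2 had no peak and Apob had 0.383, at the 5' end alone Ptprc, Ahsg, Krt1 and Krt10 had none, and in the stricter peak list Cst8 and Ahsg had none, while in windows of 2500 bp Apoa2 had 6.99 and Ahsg 0.932. All of these lists lay below the 1st percentile of random lists, at 0.165 or less. When matched on CpG they stood between percentiles 6.53 and 23.3, and with windows of 2500 bp the erythroid and epidermis lists came to 2.40 and 1.60. The brain list (10 of 15, percentile 41.9) and the skeletal muscle list (8 of 15, percentile 11.1) lay inside the limits, but the muscle list came to 0.435 with the stronger peaks and to 0.305 with the stricter peak list, and to 65.8 when matched on CpG. Their highest values were those of Syp (2.73 ± 0.89), Snap25 (2.34 ± 0.96) and Slc17a7 (1.23 ± 0.090), and of Actn3 (8.0 ± 0.50), Mylpf (7.84 ± 2.0) and Ckm (3.54 ± 0.27). Actn3, Mylpf and Ckm share their peaks with Zdhhc24, Tbc1d10b and Klc3. In windows of 500 bp Actn3 had 1.38, Ckm 0.644 and Snap25 0.636, and in windows of 2500 bp Slc17a7 had 4.41. No peak was found at Camk2a, Mog, Acta1 or Mb.

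Housekeeping genes, fixed as a positive reference, were open at 16 of 16 promoters (percentile 99.9, and 96.8 when matched on CpG) and had the highest list median, 10.03 ± 0.58 (SD, n = 2), with Rplp0 at 19.4 ± 1.2, Actb at 16.9 ± 2.0 and Ywhaz at 14.1 ± 0.99, the last with 0.196 at the 5' end alone. Olfactory and vomeronasal receptor genes were open at 18 of 1464 promoters (1.23%, percentile 0). The highest, Vmn1r4 at 6.70 ± 1.7, shared its peak with Nt5c3; Olfr373 followed at 0.760 ± 0.028 and Olfr159 at 0.755 ± 0.21, and Olfr1 and Olfr10 had no peak. Olfr373 had none at the 5' end alone, and Olfr159 none in windows of 500 bp. Hox genes, which pattern the body axis, held CpG-rich promoters, yet 20 of 39 were open in both libraries, 12 in a single library and 7 in neither. Their open share of 51.3% stood at percentile 1.05 among all random lists (0.79 with windows of 500 bp and 0.075 with the stricter peak list, but 15.2 with windows of 2500 bp and 2.58 with the 5' end alone) and at 0 among those matched on CpG, whose median was 89.7%. Taking each library by itself, and so counting the genes open in both, 64.1% had a promoter peak in replicate 1 and 69.2% in replicate 2. These shares stood at percentiles 20.9 and 42.8 among lists not matched on CpG. The median promoter value stood at percentiles 6.66 and 9.37 among such lists, inside the limits, and at 0 in both libraries among lists matched on CpG. All these percentiles count the Hox genes, which lie in clusters, as separate genes, whereas the random lists hold scattered genes. The highest were Hoxa4 at 4.9 ± 1.3, Hoxd8 at 4.39 ± 0.45 and Hoxc13 at 3.24 ± 0.38, and Hoxa11 and Hoxa2 had no peak. Hoxa13, Hoxb2, Hoxb3 and Hoxc11 had a peak in replicate 1 alone, and Hoxa3, Hoxa6, Hoxb7 and Hoxb8 in replicate 2 alone, all with values of 0.638 or less.

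**Figure D1:**
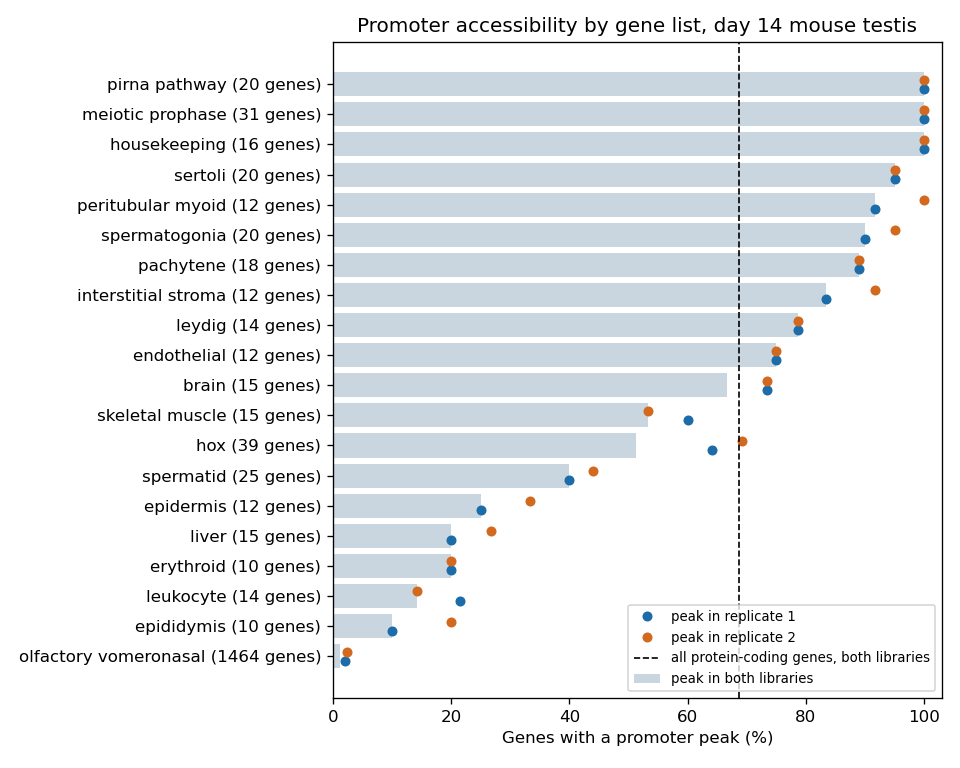
Share of genes with a promoter peak (x axis, %) in each gene list (y axis) of day 14 mouse testis. Bars give the share open in both libraries, points the share in each library, and the dashed line all protein-coding genes at 68.7%; the meiotic, piRNA and housekeeping lists reach 100% and the receptor genes 1.23%.

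Peaks outside promoters were most numerous around spermatogonial, Sertoli and Hox genes. The median gene had 4 such distal peaks within 50 kb of its transcription starts in each library. A gene with more annotated starts can cover more sequence, and the random lists were not matched on starts, gene density or CpG. Percentiles are those of the list median of each gene's mean over both libraries, which was 7.75 for the Sertoli list, 6.75 for the Leydig list and 0.5 for receptor genes, while the values with SD are means of the 2 library medians. The mean of the library medians was 7.5 ± 0.71 (SD, n = 2) for the spermatogonial list (percentile 99.5), 7.5 ± 1.4 for the Sertoli list (percentile 99.8) and 8.5 ± 0.71 for the Hox list (percentile 99.995). Hox genes lie in clusters, so the 50 kb windows of neighbours overlap and count the same peaks again. Hoxd12 and Hoxd13, for example, each had 10 and 15 distal peaks in the 2 libraries. The random lists hold scattered genes and do not allow for this, so the Hox percentile overstates the number of separate genes behind it. Leydig genes had 7.25 ± 1.8 (percentile 95.9, and 99.2 in replicate 2 alone), endothelial genes 7.0 ± 0.71 (96.4) and peritubular myoid genes 6.75 ± 1.1 (94.96). The meiotic list, though open at each promoter, had a median of 3.0 in both libraries (percentile 9.19), and the piRNA list 4.75 ± 0.35 (percentile 68.3). Receptor genes had a median of 0 in both libraries (percentile 0). The means of the library medians of the other lists ran from 2.5 for the epidermis list to 6.25 for the housekeeping list, all inside the limits. At the stricter false discovery rate the spermatogonial list came to percentile 98.4 and the Hox list to 90.55, and with the stronger peaks alone the spermatogonial list came to 93.4 and the spermatid list, at 60.6 with all peaks, to 99.1.

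Over all protein-coding genes the highest promoter value was at Dynlt1b, a dynein light chain gene on chromosome 17 (56.7 ± 3.9), followed by Dnpep (32.9 ± 6.7) and Gm21887, annotated at 170009659 to 170019281 of chromosome X (31.4 ± 14), with 21.7 and 41.1 in the 2 libraries. Next came the divergent genes Hjurp and Trpm8 (31.1 ± 0.55) and the overlapping genes 4930535I16Rik and Rragc, on opposite strands (29.8 ± 0.47), each pair with a single shared peak (that of 4930535I16Rik lay outside its window of 500 bp), and Ankhd1 (29.9 ± 5.0), Fzr1 (29.6 ± 0.54) and Eif5a (29.0 ± 1.1). The strongest peak of both libraries lay outside protein-coding genes, at chromosome X, 143482981 to 143483140, with values of 64.6 and 76.6. The number of copies of that sequence, or of the region of Gm21887, was not analysed here. The longest peaks reached 1740 bp in both libraries. In replicate 1 they overlapped the promoter windows of Rreb1 (chromosome 13, 37826181 to 37827920), Zfp36l2 and Htr1b, and places outside protein-coding genes on chromosomes Y and 6. In replicate 2 they included peaks over those of Rnf123 and Amigo3 (chromosome 9, 108053301 to 108055040), Rbpms2 and Msl1, and a peak at the same place on chromosome 6, from 30173021 to 30174660.

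Promoters held 29.2 ± 1.3% of peak midpoints (SD, n = 2), 7.30 times the share expected from the length of promoter windows. Introns held 28.2 ± 0.68%, exons 4.57 ± 0.037% and the space between genes 38.0 ± 0.61%, the last 0.656 times its expected share. Promoter peaks were also the stronger ones, with a median value of 1.09 and 0.936 in the 2 libraries against 0.452 and 0.427 between genes. Among autosomes, density was highest on chromosome 11, with 57.8 and 67.0 peaks per Mb, and lowest on chromosome 3, with 31.2 and 35.9. The X chromosome, present once in males, had 18.7 and 22.0 peaks per Mb, or 0.463 ± 0.0026 of the autosomal median, and its peaks had a median value of 0.317 and 0.298 against 0.548 and 0.513 on autosomes. Among the stronger peaks alone, those at or above the median value, the X to autosome ratio was 0.262. The Y chromosome had 0.0276 ± 0.0061 of the autosomal density. Much of the Y chromosome is repeated sequence, and how repeated reads were placed is not given in the sources used here. Whether reads of castaneus origin were lost was not examined on any chromosome.

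**Figure D2:**
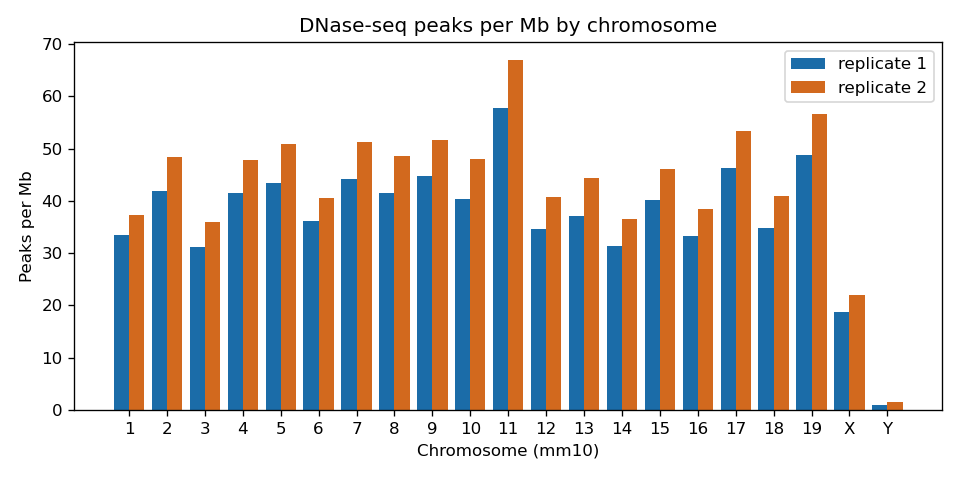
Peaks per Mb (y axis) on each mouse chromosome (x axis) in replicates 1 and 2. Chromosome 11 has the highest bars (57.8 and 67.0), X stands at 18.7 and 22.0, below all autosomes, and Y near 0.

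Footprints, short stretches protected from cutting, numbered 269247 in replicate 1 and 349555 in replicate 2, with a median width of 10 bp in both, and 85.9% and 85.0% of them touched a peak. Matches to the consensus of REST, a repressor of neuronal genes, were 8.82 ± 0.26 times (SD, n = 2) as frequent in footprints as in control windows of the same peaks. Those of CTCF, which organises chromatin loops, were 6.52 ± 0.60 times as frequent. The REST ratio rests on 10 and 11 control matches in the 2 libraries, and its SD does not measure the counting error of these. CTCF matches were in 2.02% and 1.46% of the footprints compared, and in 0.537% and 0.540% of the fewer footprints that could be compared with control windows 100 bp away. The ratio was 3.77 ± 1.1 for RFX factors, 2.57 ± 0.048 for NRF1, 2.31 ± 0.12 for NR5A1, a regulator of steroid hormone genes, 2.03 ± 0.090 for CREB and CREM, 2.00 ± 0.042 for YY1 and 1.89 ± 0.011 for SP and KLF factors. These 8 of 19 sequences exceeded 1.5 in both libraries. With footprints not extended, the mean ratio rose to 55.5 for REST, on 1 and 2 control matches, to 38.5 for CTCF, 7.61 for RFX, 5.14 for NRF1, 4.93 for NR5A1, 3.34 for CREB and CREM and 2.94 for SP and KLF factors, while that of YY1 was 1.94, so the size of most of these ratios depends on that setting. ETS (1.31 ± 0.044), E-box (1.23 ± 0.046), HNF4A (1.19 ± 0.043) and NFY (1.06 ± 0.020) sequences were slightly above 1, and the ratios of HNF4A and NFY fell below 1, to 0.969 and 0.865, when footprints were not extended. DMRT1 gave 1.08 in replicate 1 and 1.42 in replicate 2, and 0.698 and 1.33 when footprints were not extended. Sequences for MYB factors (0.793 ± 0.11), GATA factors (0.798 ± 0.080), AP1 (0.815 ± 0.084) and MEF2 (0.870 ± 0.034) were less frequent in footprints than in control windows. That of MEF2 rests on 11 and 17 footprints and rose to 3.33 with control windows 100 bp away. Control windows can overlap other footprints, so none of these ratios compares footprints with sequence free of them. The paired SOX9 and the HNF1 sequences had too few matches for a ratio.

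**Figure D3:**
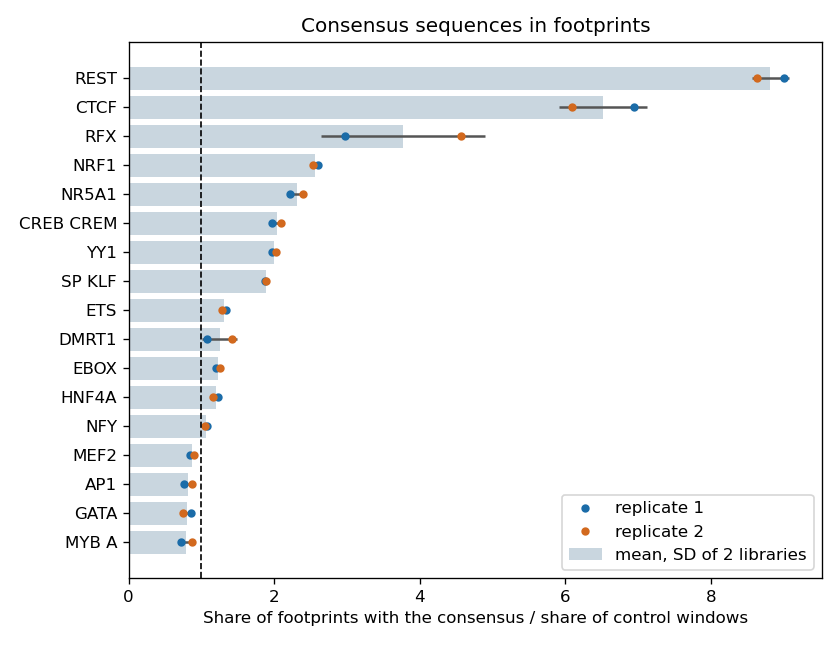
Ratio of the share of footprints with a match to the share of control windows with a match (x axis), for each consensus sequence with at least 5 control matches per library (y axis). Bars give the mean and SD of the 2 libraries and points each library. REST (8.82, on 10 and 11 control matches) and CTCF (6.52) stand apart, and the dashed line marks a ratio of 1.

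The 2 libraries shared most strong peaks and fewer weak ones. Of replicate 1's peaks 82.6% overlapped a peak of replicate 2 by at least 1 bp, and 71.4% the other way, against 1.80% and 1.55% after peaks were moved to random places on their chromosome. In the top quartile of peak values 99.1% and 97.8% were shared, in the lowest quartile 56.6% and 37.0%. Over the 83530 shared peaks the values had a Spearman correlation of 0.934 across peaks, which are not independent replicates, and 0.602% of them differed by more than 2-fold. Footprints were shared less, at 58.2% of replicate 1 and 44.1% of replicate 2, and within peaks of both libraries at 62.8% and 52.4%, against 31.4% and 26.0% after all footprints were moved to random places within shared peaks of the same chromosome. The number of footprints per peak rose with the peak value, from 0.861 to 4.10 between the lowest and highest quartile in replicate 1 and from 1.19 to 4.22 in replicate 2. Per 100 bp of peak the rise was smaller, from 0.633 to 1.70 and from 0.866 to 1.73.

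With the settings fixed beforehand, 1 of 17 gene lists, that of brain genes, lay past a limit for the difference between the libraries. Over all open genes the median of the log2 ratio of replicate 2 over replicate 1 was -0.07, and list medians are given relative to it. Brain genes were lower in replicate 2, with a median log2 ratio of -0.41 over 10 open genes (percentile 0.03 among lists matched on the mean value); the percentile was 25.7 with summed peak values, 20.5 with a window of 2500 bp and 11.1 with the stricter peak list, so the difference was past the limit in none of these 3 alternatives. Sertoli genes had 0.16 over 19 open genes (percentile 98.7), with 12 of them above the median of all open genes, and passed the limit with summed values (99.9) and with a window of 2500 bp (99.8). In that window liver genes (99.8) and receptor genes (99.96) passed it too. Spermatogonial genes had 0.11 (percentile 94.4). The other 14 lists with at least 3 open genes lay between percentiles 6.18 and 98.4, including the meiotic list at -0.04 and the Leydig list at -0.10. With 1 library on each side these values compare the libraries and have no replicate check.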

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

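The stricter FDR list was chosen after seeing the data, and the other alternatives before; where a value moved, the cause was not tested unless the alternative's construction shows it. No paired analysis was possible because there is 1 group. Leaving out a library gave no value for overlaps between the libraries or for the difference between them. In the lowest quartile of peak values 56.6% and 37.0% of peaks were shared, and whether depth sets this was not tested.

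With the stronger peaks alone, the mean number of peaks was 54793.5, the share of them found in the other library 94.6%, the X to autosome ratio 0.262 and the promoter share 41.9%. With the stricter FDR list the mean number was 65825.5 and the promoter share 37.5%. Shared peaks came to 65.9% and shared footprints to 36.6% under reciprocal overlap, the X ratio to 0.465 by covered bases and the promoter share to 22.8% with windows of 500 bp. The count of 8 consensus sequences above a ratio of 1.5 changed in no alternative but 1, where it was 9.

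Of the 20 lists 11 were past a limit at promoters, and 6 when matched on CpG. CpG matching put spermatid genes at percentile 1.985, leukocyte 6.53, erythroid 15.8, epididymis 18.1, liver 11.1, epidermis 23.3 and housekeeping 96.8, all inside the limits, and moved Leydig (99.1) and Hox genes (0) past them. A window of 2500 bp gave spermatogonia 99.35, spermatid 1.73, erythroid 2.40 and epidermis 1.60, and one of 500 bp Hox 0.79. The 5' end alone gave spermatogonia 99.5. Stronger peaks gave spermatid 1.63, Sertoli 98.7 and skeletal muscle 0.435, and the stricter list Sertoli 93.8, skeletal muscle 0.305 and Hox 0.075. With a library left out, spermatogonia ran from 97.9 to 99.5 and peritubular myoid genes from 95.2 to 99.4.

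Of distal results, stronger peaks gave spermatogonia 93.4 and spermatid genes 99.1, and the stricter list spermatogonia 98.4 and Hox 90.55, leaving 2 lists past a limit in place of 4. Leydig genes ran from 94.85 to 99.2 with a library left out.

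For the difference between the libraries, summed values put Sertoli genes at 99.9 and brain genes at 25.7. A window of 2500 bp put Sertoli at 99.8, liver at 99.8, receptor genes at 99.96 and brain at 20.5, with 3 lists past a limit in place of 1. The stricter list put brain at 11.1, with 0 lists past a limit.

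Consensus ratios crossed 1 for NFY (0.865) and HNF4A (0.969) with footprints not extended and for MEF2 (3.33) with control windows at 100 bp. In replicate 1 DMRT1 came to 0.698 with footprints not extended. Of all 68 values of consensus ratios under the alternatives, these 3 crossed 1, 42 moved by less than 1 SD and 23 by more. The 42 include 17 values for each library alone, which could not move further, since each of 2 values lies within 1 SD of their mean. With footprints not extended 2 ratios stayed within 1 SD, 13 moved by more and 2 crossed 1. With control windows at 100 bp these numbers were 6, 10 and 1. Gene lists kept their side of the limits in 137 of 160 promoter values, 95 of 100 distal values and 42 of 49 differences between the libraries. Of the named genes with a value, 16 of 76 changed by over 1.5 times with the 5' end alone, 15 with windows of 500 bp, 7 with windows of 2500 bp and 13 with the stricter list, and 11, 7, 0 and 10 of them had no peak there. With the 5' end alone these include Tdrd7 (0.174), Ywhaz (0.196) and Meioc, Egfl7, Vwf and Krt10, which had no peak there, so their peaks lie at other annotated starts.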

Other observations

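The gene families, the comparison of X with chromosomes 12 and 18, the count of settings for Sertoli genes and the motif values of shared peaks were chosen after the results they follow from had been seen; the remaining tests were written down before their own result was seen, although the joint test of copy number and CpG and the test on shared peak values were added once earlier tests were known, and the DMRT1 shares of footprints were known before any of its tests. All patterns were found and tested on the same data.

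Among gene families, taken as symbols with the same stem and at least 20 members, some were open at every member, among them 49 of 49 mitochondrial ribosomal Mrpl genes, 69 of 69 Rab genes of vesicle traffic, 37 of 37 Ddx helicases, 36 of 36 Cep centrosome genes and 30 of 30 Med genes of the Mediator complex. Other families of basic cell functions had exceptions, with 48 of 54 ribosomal Rpl, 42 of 44 Rps, 52 of 55 Eif and 24 of 27 Cox genes open. Cfap genes of cilia and flagella were open at 30 of 31 promoters and Zfp zinc finger genes at 353 of 394. At the other end, none of 25 Prl, 22 Mup, 22 Defa and 21 Lce genes had a promoter peak in both libraries, Defb genes of the beta-defensin family had 7 of 42 and the X-linked Rhox homeobox genes 8 of 34. Several of these families are tandem copies, and the placement of their reads was not examined. Over all protein-coding genes 68.7% were open. Median promoter CpG (observed over expected) ran from 0.72 to 0.80 in the fully open families named here, and from 0.064 to 0.163 in Prl, Mup, Defa and Lce. The families were not matched on CpG, so their contrast cannot be told apart from one of CpG content.

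Shared peaks with a match to the CTCF consensus were lower in replicate 2 than shared peaks of like value, by a median log2 ratio of -0.34 over 4598 peaks, of which 12.1% lay above 0, and of -0.39 when also matched on GC content. REST matches gave -0.28 over 119 peaks. In peaks of a single library, CTCF matches were in 3.97% of those of replicate 1 and 0.690% of those of replicate 2, and NR5A1 matches in 0.777% and 1.24%. NR5A1 (0.16) and GATA (0.12) matches were higher in replicate 2 in shared peaks, with smaller values of 0.12 and 0.087 when also matched on GC content.

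For the low peak density of the X chromosome, a single copy alone falls short: the share of X genes with a promoter value of at least 1 was 0.780 of the share of autosomal genes with at least 2, under the lowest autosome's 0.824. For low gene density, the test set beforehand would exclude it if promoter peaks per gene lay under the lowest autosome; the 1.25 of X was under the lowest mean, 1.26, but its gap to the lowest autosome of each library changed sign (-0.022 and 0.013), and its 2.42 distal peaks per gene lay inside the autosomal range, whose lowest value was 2.17. Only the later comparison of these distal peaks with chromosomes 12 and 18, which have as few genes per Mb and 5.29 and 5.02 such peaks, argues against it as the whole cause. The open share of X genes lay at percentile 2.27 of autosomal lists matched on CpG. With copy number allowed for as well, the share at or above the value limit (35.9%) lay at 97.7, above the matched median of 34.2%. Both together may account for the promoters at this 1 limit but were not tested at other limits or on distal peaks. The median value of open X promoters was 0.369 of that of open autosomal ones, a ratio not matched on CpG. No biological explanation, such as silencing of X in meiotic cells, could be tested with 1 group, and read placement on X was not examined.

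Sertoli promoters had a median log2 ratio of replicate 2 over replicate 1 of 0.16 relative to the median of all open genes (-0.07), with 12 of 19 genes above that median, at percentile 98.7, which is inside the limit. A larger share of Sertoli cells in that sample would also raise distal peaks near these genes; their median log2 ratio was 0.10, at percentile 91.05 of matched lists, short of the limit. Greater depth raising weak promoters is open too. The percentile among lists matched on the mean value passed 99 in 2 of 4 windows and summaries and not in the others. These settings use the same 2 libraries and gene list, and depth in reads is unknown, so their count cannot decide it. The explanations cannot be told apart with 2 libraries.

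Footprints in peaks held the DMRT1 consensus ACATTGT 1.70 times as often in replicate 2 as in replicate 1 (0.615% and 0.362%). Base composition is argued against, since none of 419 rearrangements of the same bases rose as much (percentile 100). Deeper footprint calling remains open: in the top quartile of shared peaks the ratio was 1.06. A different cell makeup of the samples, with more cells that use DMRT1, such as Sertoli cells or spermatogonia, is a candidate explanation as a hypothesis. A match does not show which factor binds the sequence. Peaks of replicate 2 alone held the sequence 1.85 times as often as those of replicate 1 alone (percentile 99.3 of the rearrangements). Shared peaks with it were higher in replicate 2 by a log2 ratio of 0.24 at like value (percentile 100), and of 0.20 when also matched on GC content. Shared peaks with CTCF and REST matches were lower in replicate 2 (-0.34 and -0.28). Whether a difference between the libraries other than cell makeup sets these shifts was not tested.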
